A study of Mus musculus with 8 samples.

How the data were processed

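Total RNA-seq and ribosome profiling libraries came from J1 mouse embryonic stem cells, wild type (WT) or with Mettl6 knocked out (KO, clone G6), grown in 2i medium with LIF and treated with cycloheximide for 10 min. Each of the 4 groups (WT and KO, total RNA and footprints) holds 2 libraries, labelled as biological replicates, and groups were read from the library titles. According to the submitters' processing notes, reads were called with CASAVA 1.8.2, aligned to mm10 with Bowtie2 and quantified with RSEM. The alignment settings and the versions of Bowtie2 and RSEM are not given in the sources used here. The deposited table holds CPM (reads of a gene scaled to the library total), which the authors derived from RSEM estimated counts, for 23818 gene symbols in 8 libraries, with no other column.

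The step between the smallest CPM values gave an estimated depth of 1301531 to 2031518 reads in total RNA and 1835677 to 2960255 reads in footprints. Only 89.2% to 90.5% of total RNA values and 67.3% to 75.1% of footprint values were whole reads within 0.01 read on that scale. Counts could therefore not be recovered for every gene, and the test planned for CPM was used. At these depths 1 read equals 0.492, 0.511, 0.768 and 0.656 CPM in the total RNA libraries and 0.338, 0.471, 0.41 and 0.545 CPM in the footprint libraries.

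Values were taken to log2(CPM + 1), and genes with a mean of at least 1 CPM over the libraries of a comparison were kept (in both kinds of library for translational efficiency). Genes were tested with limma-trend (limma 3.58.1 in R 4.3.3), with Benjamini-Hochberg adjusted p below 0.05 as the threshold. KO was compared with WT in total RNA and in footprints, each in a fit of its own 4 libraries with 2 residual degrees of freedom. Translational efficiency was tested as the interaction of genotype and kind of library in a fit of all 8 libraries, which also gave the footprint to total RNA ratio within WT. With 2 libraries per group an exact or permutation test cannot reach a small p, and the p of limma-trend rests on spread shared across genes. Log2 changes are differences on the log2(CPM + 1) scale, while folds are ratios of mean CPM.

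Gene lists fixed before any value was seen, 34 of them with at least 5 tested genes, were tested with camera at an inter-gene correlation of 0.01. They cover pluripotency, other lineages and feeder cells, stress responses, the cell cycle and histones, ribosomes and translation factors, tRNA enzymes, metabolism, imprinted and germline genes, selenoproteins, noncoding RNAs and genes with upstream reading frames. Each list was also tested with an estimated correlation and with fry. Members past the threshold were counted over all genes and with p adjusted over the list alone.

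Named genes were chosen by a rule fixed before any value was seen. It takes Mettl6 first, then in each comparison the 10 largest increases and the 10 largest decreases with an adjusted p below 0.05, both KO libraries on the same side of both WT ones and a mean of at least 5 CPM. Predicted genes, clone names, pseudogenes and accessions were left out. Where fewer than 5 genes passed in a direction, those with the smallest p were added up to 5 and named as not past the threshold. The rule adds up to 4 members per list with the smallest p, and Mettl2, Mettl8, Sars, Pou5f1, Nanog, Sox2, Klf4, Esrrb, Zfp42, Atf4, Myc and Malat1 in any case.

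Chromosomes and gene classes came from the RefSeq table of GRCm38.p6, matched by symbol for 22527 of the 23818 symbols. Coordinates, exons and coding sequences came from GENCODE vM21 (GRCm38, the same assembly as mm10). A coding sequence of at least 100 codons was matched to 19775 symbols, and the share of each of the 61 sense codons was set against the changes with Spearman's rho (in R). Sharing of sequence was measured as the number of words of 25 bases that transcripts of other genes also hold. Rn45s has no sequence in the reference used here, so sharing with it was not tested.

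The tests were tried on simulated data with 200 changed genes. Changes were planted only in genes at a mean of at least 5 CPM, in both kinds of library for translational efficiency. All genes of a kind of library had the same dispersion, taken from genes above 50 CPM, and varied independently. Recovery in the real data can therefore be lower and false calls more frequent. In total RNA 69% of 100 changes of 2-fold and 95% of 100 changes of 4-fold were recovered, with 8 calls among 12985 unchanged genes. In footprints the shares were 76% and 95%, with 7 calls among 11385, and for translational efficiency 43% and 85%, with 2 calls among 11183. Alternatives planned before any value was seen changed the filter, the pseudocount, the normalization, the block, the libraries in the fit and the libraries left out. For the serine share one was the partial correlation given coding length and third-position GC. Others, chosen after the data were seen, left Rn45s out of the library total, left out the genes of chromosomes 6, 8 and 11, removed the median of every chromosome, removed a trend with transcript length, put the gene lists through quantile normalization, varied the settings of the chromosome medians, or took partial correlations given transcript length or proline share. Scripts were written in R and in Python 3.11.15 (pandas 2.3.3, matplotlib 3.10.9).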

Results

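Mouse embryonic stem cells of the J1 line, either wild type (WT) or a knockout (KO) of Mettl6 in the clone called G6, were grown in 2i medium with LIF and treated for 10 min with cycloheximide, which halts elongating ribosomes, before lysis. METTL6 is a methyltransferase that places the m3C mark on tRNA, and the comparisons ask how RNA levels and translation differ in cells that lack it. Each genotype was measured by total RNA-seq and by ribosome profiling, which sequences the RNA fragments that ribosomes shield from nuclease. There were 2 libraries of each kind per genotype, labelled as biological replicates, and 8 libraries in all. The table holds CPM, the reads of a gene scaled to the library total, for 23818 gene symbols, of which 6485 were at 0 in every library.

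Read depth, estimated from the smallest step between values, was 2031518 and 1957674 reads in the WT total RNA libraries and 1301531 and 1524097 reads in the KO ones. Footprint libraries held 2960255 and 2124895 reads in WT and 2437859 and 1835677 reads in KO. Rn45s, the precursor of ribosomal RNA, took 2.49% and 6.46% of WT total RNA, 5.77% and 3.38% of KO total RNA, 46.3% and 41.3% of WT footprints, and 38.3% and 42.6% of KO footprints. Replicates of one genotype correlated across genes at r = 0.969 (WT) and 0.935 (KO) in total RNA, where WT against KO pairs gave 0.916 to 0.925. In footprints the replicates gave 0.972 (WT) and 0.969 (KO) and the WT against KO pairs 0.924 to 0.938. The knockout is a single clone, so its genotype and its history as a clone cannot be told apart, and the titles of the WT total RNA libraries carry a suffix that the KO titles lack.

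Mettl6 itself (chromosome 14, 31473578 to 31495040, minus strand, GRCm38) stood at 25.6 and 27.1 CPM in the WT total RNA libraries, at 2.30 CPM in 1 KO library, and was listed at 0 in the other. Its total RNA fell by 3.91 on the log2(CPM + 1) scale (SE 0.599, limma-trend with Benjamini-Hochberg adjusted p = 0.000367). Mettl6 footprints did not follow, at 3.38 and 6.59 CPM in WT and 5.33 and 4.36 CPM in KO (log2 change 0.015, SE 0.393, adjusted p = 0.985). Mettl6 overlaps Eaf1, on the opposite strand, over 642 bp (31494399 to 31495040), of which 139 bp are exonic in both genes, and Eaf1 was at 59.1 and 61.8 CPM in WT and 61.5 and 68.9 CPM in KO total RNA.

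In total RNA, Bhmt, the enzyme that makes methionine from betaine and homocysteine (chromosome 13, 93616675 to 93637961), fell 11.7-fold, from 315.5 ± 8.40 CPM in WT to 27.1 ± 3.01 CPM in KO cells (SD, n = 2, limma-trend adjusted p = 5.45e-09). Limch1, an actin-associated protein, rose 17.1-fold, from 5.24 ± 1.64 to 89.4 ± 8.05 CPM (SD, n = 2, adjusted p = 7.04e-07). Among genes of the feeder and fibroblast or primitive endoderm lists, Fn1 (fibronectin) rose 3.01-fold to 2240 ± 186 CPM, Lamc1 (laminin gamma chain) 2.66-fold to 1732 ± 103 CPM, Cyr61 6.87-fold to 104.9 ± 23.4 CPM and Ctgf 6.30-fold to 69.3 ± 7.80 CPM (SD, n = 2). Hist1h1b, a linker histone, fell from 572.5 ± 64.1 to 256.8 ± 29.1 CPM (SD, n = 2, adjusted p = 2.55e-05).

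Other large increases in total RNA were those of Fgfr2, a fibroblast growth factor receptor (14.8-fold, log2 change 3.21, adjusted p = 0.000434), Npnt, the matrix protein nephronectin (11.6-fold), Cyp2b23, a cytochrome P450 (11.7-fold), and Pkhd1, the gene of fibrocystin (15.8-fold). Zscan4c, a marker of the 2-cell-like state, was listed at 0 in 1 WT library and at 0.383 CPM in the other, against 25.5 and 13.9 CPM in KO (log2 change 4.08, SE 0.624, adjusted p = 0.000366). Matn1, which encodes the cartilage matrix protein matrilin, was listed at 0 in both WT libraries and stood at 3.84 and 19.03 CPM in KO (adjusted p = 0.01). Grin2a, a subunit of the NMDA receptor (log2 change 2.96), Zan (3.17) and the readthrough gene Rbm14-rbm4 (3.19) completed the 10 largest. Among the 10 largest decreases after Mettl6 were Krt42, a keratin (log2 change −3.57, 14.3 CPM in both WT libraries, 0 and 0.656 CPM in KO) and Magohb, a component of the exon junction complex (−3.41). The others were Xlr5a (−3.29), Bet1, a SNARE of the Golgi (−2.86), Klhl23 (−2.79), Hist3h2ba, an H2B histone (−2.67), Acap1 (−2.59) and Ccnjl (−2.58). Krt42, Hist3h2ba, Acap1 and Ccnjl lie on chromosome 11, and Magohb and Bet1 on chromosome 6. Some of these calls depended on the handling of low values. With no filter on low values the adjusted p was 0.051 for Matn1, 0.179 for Rbm14-rbm4, 0.0608 for Bet1, 0.102 for Klhl23 and 0.106 for Ccnjl, and with a pseudocount of 0.1 it was 0.0973 for Rbm14-rbm4, 0.0705 for Klhl23 and 0.0793 for Ccnjl.

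Over all genes, limma-trend called 1799 of 13222 genes in total RNA at an adjusted p below 0.05, 869 higher and 930 lower in KO, and 3689 genes had an unadjusted p below 0.05. Of the called genes, 419 rose and 295 fell by a log2 change of at least 1, and the median standard error of a log2 change was 0.326. With any 1 of the 4 libraries left out, the fit had 1 residual degree of freedom and limma-trend called 0 genes, with 1863 to 3655 genes at an unadjusted p below 0.05. A fit that took its spread from all kinds of library called 1941 of 11364 genes with all 8 libraries, and fewer with any 1 library left out.

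Genes of chromosomes 6, 8 and 11 lay lower in KO as a body, a pattern found after the data were examined. These chromosomes were grouped because their medians lay below −0.3 in both kinds of library. Their median log2 changes in total RNA were −0.41, −0.39 and −0.44, against −0.0996 to 0.103 on the other chromosomes, and in footprints they were −0.43, −0.39 and −0.46, against −0.0613 to 0.0647. Every pairing of a KO with a WT library gave the same sign. Less the median of all other genes, the medians of these chromosomes ran from −0.473 to −0.325 over the pairs in total RNA and from −0.46 to −0.334 in footprints. These chromosomes held 2431 of the tested genes in total RNA (18.4%), 499 of the 930 lower calls (53.7%) and 41 of the 869 higher calls, and in footprints they held 578 of the 963 lower calls (60%). The adjusted p of camera was 9.09e-11 for chromosome 11, 2.63e-08 for chromosome 6 and 1.03e-06 for chromosome 8 in total RNA. With an estimated correlation none passed (adjusted p = 0.497, 0.497 and 0.509). Without the genes of these chromosomes, limma-trend called 1182 of 10791 genes in total RNA, 783 higher and 399 lower. With each chromosome's median removed it called 961 genes higher and 731 lower.

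**Figure D1:**
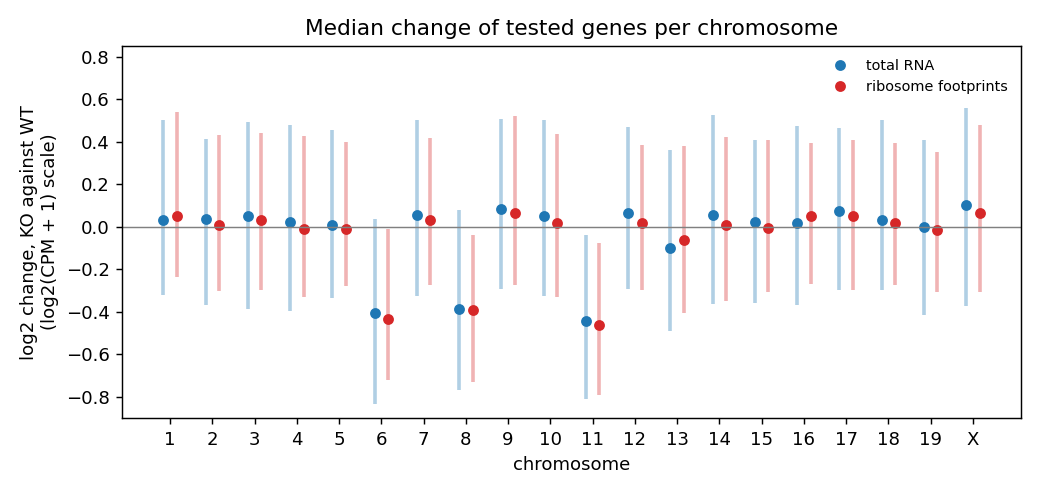
Median log2 change of KO against WT (vertical axis, log2(CPM + 1) scale) of the genes tested on each chromosome (horizontal axis), with bars from the lower to the upper quartile, in total RNA (blue) and ribosome footprints (red). The medians of chromosomes 6, 8 and 11 lie between −0.464 and −0.388, and those of the other chromosomes between −0.0996 and 0.103.

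Among lists of genes fixed before the data were examined, 17 of 34 passed camera in total RNA, 7 higher and 10 lower. In the primitive endoderm list 6 of 14 tested genes rose and 0 fell (9 and 0 adjusted over the list alone), with a median log2 change of 1.02 (adjusted p = 4.78e-05, and adjusted p = 0.319 with an estimated correlation). Among the members that rose were Lamc1, Lama1 (2.10-fold), Col4a1 (2.64-fold, on chromosome 8) and Serpinh1 (1.95-fold), the collagen chaperone, whereas the transcription factor Gata6 stood between 0 and 3.84 CPM in total RNA and Sox17 between 0 and 1.02 CPM. In the feeder and fibroblast list 5 of 10 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 1.05 (adjusted p = 6.7e-06, and adjusted p = 0.319 with an estimated correlation). They included Fn1, Cyr61, Ctgf and Col5a1 (2.37-fold), while Col1a1, the main collagen of fibroblasts, stood between 0 and 1.54 CPM in total RNA. Of 25 p53 targets, 7 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.43, adjusted p = 5.57e-05, and adjusted p = 0.319 with an estimated correlation), among them Plk2 (2.49-fold), Eda2r (1.99-fold), Mdm2, the ubiquitin ligase of p53 (1.70-fold), and Trp53inp1. The unfolded protein response list had 7 of 20 genes up and 1 down (7 and 2 adjusted over the list alone, median 0.25, adjusted p = 0.0145, and adjusted p = 0.693 with an estimated correlation). Increases were led by the endoplasmic reticulum chaperones Pdia3 (1.85-fold) and Hspa5 (1.41-fold) and by Syvn1 (2.57-fold). Imprinted genes had 4 of 21 up and 1 down (5 and 2 adjusted over the list alone, median 0.38, adjusted p = 0.026, and adjusted p = 0.326 with an estimated correlation), among them Igf2r (1.76-fold) and Peg10 (1.75-fold). Noncoding RNAs had 8 of 23 up and 3 down (10 and 3 adjusted over the list alone, median 0.66, adjusted p = 8.29e-05, and adjusted p = 0.326 with an estimated correlation). Kcnq1ot1 rose 2.57-fold, Malat1 1.64-fold and Xist 2.98-fold, from 68.7 ± 16.1 to 204.4 ± 44.2 CPM (SD, n = 2), whereas Rpph1 fell 1.51-fold. The 2-cell-like list had a median of 1.28 over 14 genes, of which Zscan4c alone was called, also when adjusted over the list alone (adjusted p = 0.0044, and adjusted p = 0.468 with an estimated correlation).

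The 10 lists lower in KO total RNA covered histones, the cell cycle, the translation machinery and stress chaperones. Replication-dependent histones had 22 of 28 genes down and 0 up (25 and 0 adjusted over the list alone), with a median log2 change of −0.81 (adjusted p = 1.7e-19, and adjusted p = 0.319 with an estimated correlation). Hist4h4, on chromosome 6, fell 3.07-fold, and Hist1h4d and Hist2h2bb, on chromosomes 13 and 3, fell 2.07-fold and 1.98-fold. For S phase genes the counts were 9 of 33 down and 0 up (17 and 1 adjusted over the list alone, median −0.41, adjusted p = 1.55e-05, and adjusted p = 0.319 with an estimated correlation). Rpa1, Mcm2, Cdc6 and Mcm5, all on chromosomes 6, 8 or 11, fell 1.95-fold, 1.89-fold, 1.72-fold and 1.49-fold, and without the genes of these chromosomes 4 of 27 S phase genes fell (median −0.338). Mitosis genes had 5 of 28 down and 1 up (7 and 1 adjusted over the list alone, median −0.28, adjusted p = 0.000716, and adjusted p = 0.326 with an estimated correlation). Top2a, topoisomerase II, and Mad2l1, a checkpoint protein, fell 1.95-fold and 2.02-fold, while Mki67 rose 1.55-fold. Top2a and Mad2l1 are the 2 of the 5 lower calls that lie on chromosomes 6, 8 or 11.

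Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, had 10 of 22 genes down and 1 up in total RNA (14 and 2 adjusted over the list alone), with a median of −0.44 (adjusted p = 6.7e-06, and adjusted p = 0.326 with an estimated correlation). Kars and Aars on chromosome 8 fell 2.25-fold and 1.87-fold, Gars on chromosome 6 fell 1.79-fold, and Nars on chromosome 18 fell 1.55-fold. Initiation factors had 10 of 37 down and 0 up (13 and 1 adjusted over the list alone, median −0.28, adjusted p = 0.000117, and adjusted p = 0.319 with an estimated correlation). Eif4a1 on chromosome 11 fell 1.72-fold, and Eif2s2 and Eif3d on chromosomes 2 and 15 fell 1.49-fold and 1.75-fold. Elongation and termination factors had 4 of 19 down and 1 up, the same counts when adjusted over the list alone (median −0.19, adjusted p = 0.0273, and adjusted p = 0.326 with an estimated correlation). Abce1 fell 1.90-fold and Eef1a1 1.29-fold, and Pabpc1, the poly(A)-binding protein, rose 1.93-fold. Of the 4 lower calls of this list, 2 lie on chromosomes 6, 8 or 11. Large-subunit ribosomal proteins had 14 of 47 down and 0 up (15 and 0 adjusted over the list alone, median −0.12, adjusted p = 0.000347, and adjusted p = 0.698 with an estimated correlation). The 4 with the smallest p, Rpl27, Rpl32, Rpl26 and Rpl13, lie on chromosomes 6, 8 or 11, as do 8 of the 14, and without the genes of these chromosomes 5 of 37 fell (median −0.0321). Mitochondrial ribosomal proteins had 10 of 76 down and 1 up (14 and 1 adjusted over the list alone, median −0.43, adjusted p = 0.000117, and adjusted p = 0.468 with an estimated correlation). Of these 10, 7 lie on chromosomes 6, 8 or 11, and without the genes of those chromosomes 3 of 57 fell (median −0.306). Ribosome biogenesis genes had 7 of 35 down and 0 up (12 and 1 adjusted over the list alone, median −0.32, adjusted p = 4.85e-05, and adjusted p = 0.319 with an estimated correlation), among them Npm1 (1.74-fold) and Nop2 (1.89-fold), and 2 of 26 fell without the genes of those chromosomes. Heat shock genes had 4 of 18 down and 1 up (5 and 1 adjusted over the list alone, median −0.27, adjusted p = 0.026, and adjusted p = 0.326 with an estimated correlation). Stip1 fell 1.43-fold and Hspb1 rose 1.67-fold.

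All 17 list calls in total RNA held with chromosome medians removed, and 15 held without the genes of chromosomes 6, 8 and 11, where the imprinted and the elongation lists were lost. The lower lists that held without these genes had fewer members down among fewer tested genes. Initiation factors had 9 of 34 down (10 of 37 with all genes), and aminoacyl-tRNA synthetases 7 of 17 (10 of 22). Mitosis genes had 3 of 24 down (5 of 28), heat shock genes 3 of 16 (4 of 18) and histones 21 of 27 (22 of 28). With an estimated correlation 0 lists passed, 4 had an unadjusted p below 0.05, and fry, which tests whether a list's genes move one way, called 10, with 17 at an unadjusted p below 0.05. With the trend with transcript length removed 14 held, and the large-subunit ribosomal, heat shock and elongation lists were lost, while quantile normalization lost heat shock. Without KO replicate 2, 12 of the 17 held, with the 2-cell-like, heat shock, imprinted, elongation and unfolded protein response lists lost. The large-subunit ribosomal and elongation lists were lost without KO replicate 1 and the unfolded protein response without WT replicate 2. Of the lists not called, naive pluripotency had 2 of 30 genes up and 5 down (median 0.01, adjusted p = 0.958), with Nanog (chromosome 6), Dppa3 (chromosome 6) and Zfp42 (chromosome 8) down 1.71-fold, 2.19-fold and 1.49-fold and Sall4 up 1.73-fold. All 5 lower calls of the naive pluripotency list lie on chromosomes 6, 8 or 11, and without the genes of these chromosomes 2 of 23 rose and 0 fell (median 0.143). Zfp42 was no longer called once chromosome medians were removed (log2 change −0.21, adjusted p = 0.219). Pou5f1 (440 ± 47.3 and 412 ± 29.7 CPM), Sox2, Klf4 and Esrrb, core pluripotency factors, had log2 changes of −0.09, 0.14, 0.12 and −0.07 and were not called (SD, n = 2). The integrated stress response list had 3 of 34 genes up and 3 down (adjusted p = 0.958), with Asns, on chromosome 6, down 1.78-fold and the amino acid transporter Slc7a3 up 1.94-fold, and its regulator Atf4 was not called (log2 change −0.26, adjusted p = 0.219). Fatty acid synthesis genes went both ways, 3 of 18 up and 8 down (adjusted p = 0.181). The other tRNA m3C enzymes and their partners had 0 of 5 genes called (0 up and 1 down adjusted over the list alone). Among them were Mettl2 (log2 change −0.40), Mettl8 (0.39), Dalrd3 (0.46) and Sars, the seryl-tRNA synthetase (−0.50, limma-trend adjusted p = 0.0557). Sars passed in 4 other settings of filter or scaling, with adjusted p from 0.0248 to 0.045. Myc stood between 0 and 2.55 CPM in total RNA and was not tested.

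Median and test differed in sign for neuroectoderm genes (median 0.29, test down). Median and mean differed for naive pluripotency (0.01 and −0.02), the integrated stress response (−0.11 and 0.03), small-subunit ribosomal proteins (−0.03 and 0.01) and immediate-early genes (−0.17 and 0.07), whose tests pointed up, down, up and up. The remaining lists did not pass in total RNA. They were formative pluripotency (4 of 17 up, 0 down, adjusted p = 0.248), with Fst up 8.68-fold and Dnmt3b 2.04-fold, and trophoblast (2 of 12 up, 0 down, adjusted p = 0.374). Neuroectoderm (1 of 8 up, 1 down, adjusted p = 0.958), with Nes down 2.36-fold, and mesoderm and primitive streak (0 of 7 called by limma-trend, adjusted p = 0.958) are further markers of lineages. Lists of translation were small-subunit ribosomal proteins (2 of 32 up, 1 down, adjusted p = 0.958), and tRNA modification enzymes (2 of 55 up, 4 down, adjusted p = 0.248). Lists of metabolism were oxidative phosphorylation (2 of 53 up, 2 down, adjusted p = 0.673), glycolysis (1 of 24 up, 3 down, adjusted p = 0.477), with the glucose transporter Slc2a1 up 2.40-fold, and cholesterol synthesis (2 of 23 up, 3 down, adjusted p = 0.205). The others were immediate-early genes (1 of 13 up, 1 down, adjusted p = 0.673) and germline genes sensitive to DNA methylation (0 of 19 up, 2 down, adjusted p = 0.4). Also not called were selenoproteins (4 of 18 up, 0 down, adjusted p = 0.0877) and genes buffered by upstream reading frames (2 of 17 up, 1 down, adjusted p = 0.57).

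**Figure D2:**
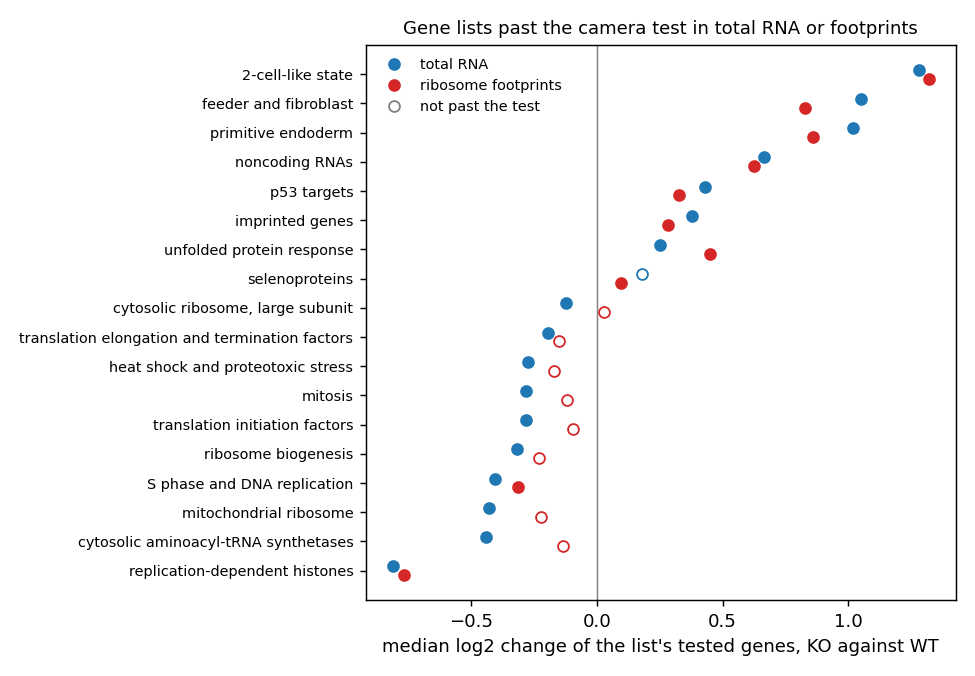
Median log2 change of KO against WT (horizontal axis) of the tested genes of each list that passed camera in total RNA (blue) or ribosome footprints (red), 1 list per line, with open circles where the list did not pass. Histones lie lowest in both kinds of library (−0.81 and −0.77), and the primitive endoderm (1.02 and 0.86) and feeder (1.05 and 0.83) lists stand near 1.

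In ribosome footprints, Slc5a1, the sodium-glucose cotransporter (chromosome 5, 33104219 to 33162870), rose 12.9-fold, from 4.55 ± 0.222 CPM in WT to 58.7 ± 0.113 CPM in KO (SD, n = 2, limma-trend adjusted p = 7.24e-13). Pros1 (protein S of coagulation) rose 8.01-fold to 93.3 ± 11.3 CPM, F2r (the thrombin receptor) 7.45-fold to 95.5 ± 0.172 CPM, Vcan (the proteoglycan versican) 7.47-fold to 68.0 ± 7.91 CPM, and Slc13a5 (a citrate transporter) 8.24-fold to 40.8 ± 7.80 CPM (SD, n = 2). Bhmt fell 7.19-fold, from 228.2 ± 46.1 to 31.7 ± 8.0 CPM (SD, n = 2, adjusted p = 1.27e-13). Footprints of Hist2h3c1, a histone gene, fell from 1205 ± 80.8 to 505.6 ± 115 CPM (SD, n = 2, adjusted p = 8.08e-07).

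Among the other large increases, Tmppe, a metallophosphoesterase, rose 8.70-fold and Cd109, a surface glycoprotein, 10.4-fold, while Vnn1, a pantetheinase, was listed at 0 in both WT footprint libraries and stood at 8.61 and 13.1 CPM in KO (adjusted p = 2.93e-07). Reads assigned to Mir6240 (chromosome 5, 114851948 to 114852064) rose 18.3-fold, from 185 and 343 to 4793 and 4861 CPM, with Mir6240 listed at 0 in the total RNA libraries. Reads assigned to Mir6481, also listed at 0 in total RNA, went from 2.36 and 10.8 to 28.3 and 118 CPM, and its call was lost without WT footprint replicate 1 (adjusted p = 0.063). Decreases after Bhmt were those of Grb7, a signalling adaptor (log2 change −2.77), Esx1, an X-linked homeobox gene (8.06-fold, from 28.7 ± 8.63 to 3.55 ± 0.376 CPM; SD, n = 2), and Map7d2, a microtubule-associated protein (5.88-fold). Smaller ones were those of Adam23 (5.49-fold), Padi2, a peptidylarginine deiminase (4.42-fold), Zswim7 (4.85-fold), Cldn7, a claudin of tight junctions (4.22-fold), Tex14 (4.48-fold) and Crygd, a lens crystallin (3.62-fold). Grb7, Zswim7, Cldn7 and Tex14 lie on chromosome 11, as does Slc13a5. Some of these calls were lost with 1 library left out. Without WT replicate 1 the adjusted p was 0.07 for Grb7, 0.0784 for Padi2, 0.0533 for Tex14 and 0.0768 for Crygd. Without WT replicate 2 it was 0.0573 for Grb7, 0.0578 for Adam23, 0.135 for Padi2, 0.171 for Tex14 and 0.118 for Crygd. Without KO replicate 1 it was 0.0645 for Padi2 and 0.0569 for Crygd, and without KO replicate 2 it was 0.103 for Tex14.

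Over all genes, 2205 of 11624 were called in footprints, 1242 higher and 963 lower, and 3613 had an unadjusted p below 0.05. Of the called genes, 685 rose and 369 fell by a log2 change of at least 1. The split depended on the scaling: with CPM recomputed without Rn45s, 1172 genes were higher and 1514 lower, and with chromosome medians removed, 1375 were higher and 679 lower. Without the genes of chromosomes 6, 8 and 11 the counts were 1074 higher and 335 lower of 9451 tested. Leaving out 1 library lowered the count to 746 (WT replicate 1), 837 (WT replicate 2), 1064 (KO replicate 1) or 574 (KO replicate 2).

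Of the same 34 lists, 10 passed camera in footprints, 8 higher and 2 lower. Primitive endoderm genes had 9 of 13 up and 1 down (10 and 1 adjusted over the list alone, median log2 change 0.86, adjusted p = 7.99e-06, and adjusted p = 0.852 with an estimated correlation), with Lamc1 up 2.90-fold, Lama1 2.77-fold and Col4a1 2.11-fold. In the feeder and fibroblast list 6 of 11 rose and 1 fell, the same counts when adjusted over the list alone (median 0.83, adjusted p = 1.38e-05, and adjusted p = 0.828 with an estimated correlation). Cyr61 led the increases (6.69-fold), before Ctgf (5.96-fold) and Fn1 (2.96-fold, to 5004 ± 49.8 CPM; SD, n = 2). Unfolded protein response genes had 9 of 20 up and 1 down (9 and 2 adjusted over the list alone, median 0.45, adjusted p = 0.000156, and adjusted p = 0.938 with an estimated correlation). Hspa5 rose 2.07-fold, Hsp90b1 1.93-fold, Syvn1 2.32-fold and Pdia3 1.86-fold. For p53 targets the counts were 6 of 24 up and 0 down (7 and 0 adjusted over the list alone, median 0.33, adjusted p = 0.00232, and adjusted p = 0.828 with an estimated correlation), with Plk2 up 4.13-fold and Perp, a desmosome protein, 3.29-fold. Imprinted genes had 4 of 19 up and 0 down (4 and 0 adjusted over the list alone, median 0.28, adjusted p = 0.0145, and adjusted p = 0.828 with an estimated correlation), with Igf2r up 2.25-fold. Selenoproteins had 5 of 17 up and 0 down (5 and 0 adjusted over the list alone, median 0.10, adjusted p = 0.0405, and adjusted p = 0.828 with an estimated correlation). Dio3, a deiodinase, rose 7.62-fold, Selt 2.27-fold and Ept1 2.45-fold. The 2-cell-like list had 3 of 5 up and 0 down, also when adjusted over the list alone (median 1.32, adjusted p = 0.0497, and adjusted p = 0.828 with an estimated correlation).

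Among noncoding RNAs, fragments in the footprint libraries rose for 5 of 19 and fell for 0 (5 and 0 adjusted over the list alone, median 0.63, adjusted p = 0.000168, and adjusted p = 0.952 with an estimated correlation). Kcnq1ot1 rose 5.67-fold, Rpph1 3.96-fold, Rmrp 3.03-fold, from 739.8 ± 401 to 2242 ± 47.0 CPM, and Malat1 2.35-fold (SD, n = 2). The Malat1 call was lost without WT replicate 1 (adjusted p = 0.0605) or KO replicate 2 (0.085). Histones had 24 of 28 down and 0 up (25 and 0 adjusted over the list alone, median −0.77, adjusted p = 1.08e-18, and adjusted p = 0.828 with an estimated correlation). S phase genes had 5 of 33 down and 0 up (5 and 0 adjusted over the list alone, median −0.32, adjusted p = 0.002, and adjusted p = 0.958 with an estimated correlation), and Cdc6, on chromosome 11, fell 2.35-fold. Of these 5, 4 lie on chromosomes 6, 8 or 11, and 1 of 27 fell without the genes of these chromosomes (median −0.262, adjusted p = 0.00663). With chromosome medians removed 9 of the 10 lists held (the 2-cell-like list was lost), and without the genes of chromosomes 6, 8 and 11 the selenoprotein list was lost too, leaving 8. With an estimated correlation 0 lists passed and 0 had an unadjusted p below 0.05, and fry called 0, with 10 at an unadjusted p below 0.05. The selenoprotein list was lost with each of the 4 libraries left out and with quantile normalization. Quantile normalization lost the 2-cell-like list too, as did leaving out either WT replicate or KO replicate 1. Without KO replicate 2, 6 of the 10 lists held, and the imprinted, noncoding and S phase lists were lost as well.

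Footprints of Nanog, Dppa3 and Zfp42 fell 1.74-fold, 2.82-fold and 1.47-fold, those of Sall4 and Nr0b1 rose 1.68-fold and 2.43-fold, and naive pluripotency as a list had 7 of 30 genes up and 5 down (adjusted p = 0.619). Zfp42 was lost with chromosome medians removed (adjusted p = 0.484) and without WT replicate 2, KO replicate 1 or KO replicate 2 (0.211, 0.114 and 0.222), and Nanog without KO replicate 2 (0.0961). Mettl2, on chromosome 11 (105126425 to 105140394), which makes m3C on other tRNAs, fell 2.74-fold in footprints, from 23.8 ± 3.18 to 8.69 ± 0.37 CPM (SD, n = 2, adjusted p = 0.000411, and 0.0597 without WT replicate 2). Pou5f1, Sox2, Klf4, Esrrb, Atf4, Mettl8 and Sars had log2 changes of 0.12, 0.00, −0.34, −0.15, −0.36, −0.13 and −0.05 in footprints and were not called, though Atf4 passed with CPM recomputed without Rn45s (−0.45, adjusted p = 0.0478). The integrated stress response list went both ways, 9 of 33 up and 5 down (median −0.16, mean 0.07, test up, adjusted p = 0.648), with Slc7a3 up 2.65-fold. Aminoacyl-tRNA synthetases had 2 of 22 up and 3 down in footprints (median −0.14, adjusted p = 0.48), and large-subunit ribosomal proteins 2 of 47 up and 2 down (median 0.03, adjusted p = 0.797).

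Changes in total RNA and footprints went together. Across the 11364 genes tested in both, the log2 changes correlated at Pearson r = 0.610 and Spearman rho = 0.581, where genes are not independent replicates. Of 919 genes called in both kinds of library, 917 changed in the same direction, 515 up and 402 down, against 86.5 and 77.3 from independent lists. Among these were Bhmt, Limch1, Fn1, Lamc1, Cyr61 and Nanog. Of 1733 total RNA calls tested in footprints, 1624 (93.7%) had a footprint change of the same sign.

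**Figure D3:**
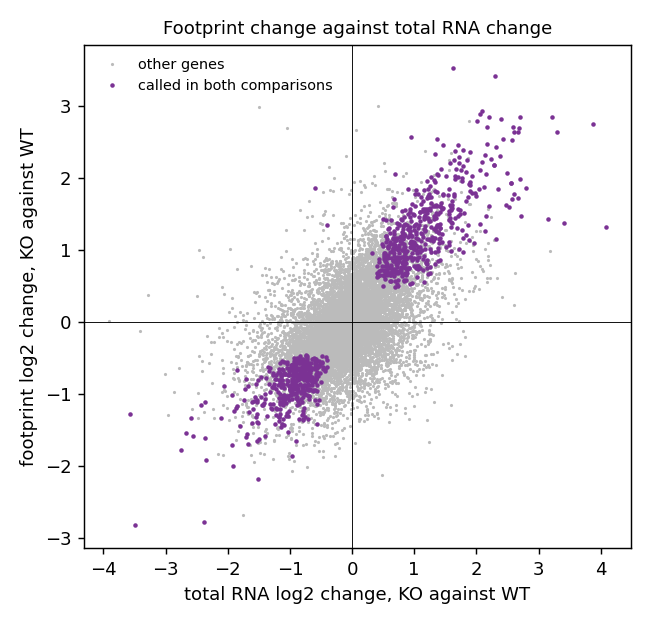
Log2 change in ribosome footprints (vertical axis) against log2 change in total RNA (horizontal axis), KO against WT on the log2(CPM + 1) scale, 1 point per gene tested in both. The 919 genes called in both comparisons are purple and all but 2 lie where both changes have the same sign (r = 0.610 over 11364 genes).

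Translational efficiency, the footprint change beyond the total RNA change, was tested as the interaction of genotype and kind of library in all 8 libraries. Srrm2, a scaffold of splicing speckles (chromosome 17, 23790532 to 23824741), rose in total RNA from 492 ± 6.97 to 1181 ± 227 CPM while its footprints stood at 355 ± 15.5 and 344 ± 14 CPM (SD, n = 2). Its interaction was −1.29 (SE 0.218, adjusted p = 0.0122). Lars2, the mitochondrial leucyl-tRNA synthetase (chromosome 9, 123366927 to 123462666), rose in footprints from 1248 and 1797 to 8495 and 11096 CPM (adjusted p = 1.83e-12), with an interaction of 3.75 (SE 0.692, adjusted p = 0.0225). Its total RNA was 1073 and 6594 CPM in WT and 2496 and 660 CPM in KO. Rpph1, the RNA component of RNase P, had an interaction of 2.47 (SE 0.313, adjusted p = 0.000194), and Mettl6 one of 3.93 (SE 0.721, adjusted p = 0.0225). Rpph1 is a noncoding RNA, so its interaction compares kinds of library and does not measure translation.

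In all, 7 of 11364 genes were called for translational efficiency, 5 higher and 2 lower, with 1013 at an unadjusted p below 0.05 and a median standard error of 0.418. With 1 library left out the count ran from 2 to 8, except for 46 without KO total RNA replicate 2 and 27 without WT footprint replicate 2. With CPM recomputed without Rn45s, 5 of 12 called genes were higher and 7 lower. Of the 7 genes called in the main fit, 4 are protein coding by RefSeq class. Besides Mettl6, Lars2, Rpph1 and Srrm2, the other 3 fall outside the rule for named genes and were singled out after their values were seen. They were Gm20594 (2.62, SE 0.337, adjusted p = 0.000194), 6820431F20Rik (1.72, SE 0.308, adjusted p = 0.022) and 4930470H14Rik (−1.44, SE 0.284, adjusted p = 0.0476). Their footprints stood at 39.95 ± 20.5, 6.28 ± 2.04 and 2.53 ± 0.49 CPM in KO (SD, n = 2). Their reads can be shared, since 61 of 425 words of 25 bases in Gm20594 also occur in the mitochondrial ribosomal RNA mt-Rnr2. Likewise 1274 of 4982 words of 6820431F20Rik and 860 of 1710 words of 4930470H14Rik occur in other genes, and 209 of 295 words of Rpph1 lie in Ccnb1ip1, which overlaps it. Mettl6 shares 987 of 7833 words with other genes, Lars2 212 of 11142 and Srrm2 571 of 12941. Shares of words do not bound shares of reads. Sharing with Rn45s, which took 38.3% to 46.3% of footprint reads, was not tested, so how uncertain these values are is not known.

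Single libraries decided some of these calls. Mettl6 was lost without WT total RNA replicate 1 or 2 (adjusted p = 0.152 and 0.275), WT footprint replicate 1 (0.309), KO footprint replicate 1 (0.152) or 2 (0.167). Lars2 was lost without WT total RNA replicate 2 (0.262), WT footprint replicate 1 (0.309), KO footprint replicate 1 (0.14) or 2 (0.296). Srrm2 was lost without WT total RNA replicate 1 or 2 (0.0698 and 0.149), KO total RNA replicate 1 (0.089), KO footprint replicate 1 (0.0612) or 2 (0.146). Rpph1 passed with each library left out in turn. Other settings ended calls too. A limma fit of footprint to total RNA ratios per replicate number gave an adjusted p of 0.67 for Mettl6, Lars2, Rpph1 and Srrm2. The replicate numbers were not shown to pair. With no filter on low values the adjusted p was 0.0766 for Mettl6 and 0.108 for Lars2, with a pseudocount of 0.1 it was 0.388, 0.277 and 0.0539 for Mettl6, Lars2 and Srrm2, and with quantile normalization it was 0.123 for Lars2. The next genes by p did not pass: Chd4, a chromatin remodeller (−1.002, adjusted p = 0.0785), Zfp277 (−1.36, 0.112), Pabpc1 (−1.01, 0.112), Zfhx3 (−1.65, 0.112), Ccdc47 (1.13, 0.142) and Eno1b (1.38, 0.142). Chd4 passed with CPM recomputed without Rn45s (adjusted p = 0.00336), as did Zfp277 (0.0288) and Pabpc1 (0.0157). All 3 also passed with median centring, chromosome medians removed or the length trend removed, and Chd4 and Zfp277 with a pseudocount of 5 or quantile normalization. None of the 3 passed with no filter on low values, at 10 CPM or more or with a pseudocount of 0.1.

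**Figure D4:**
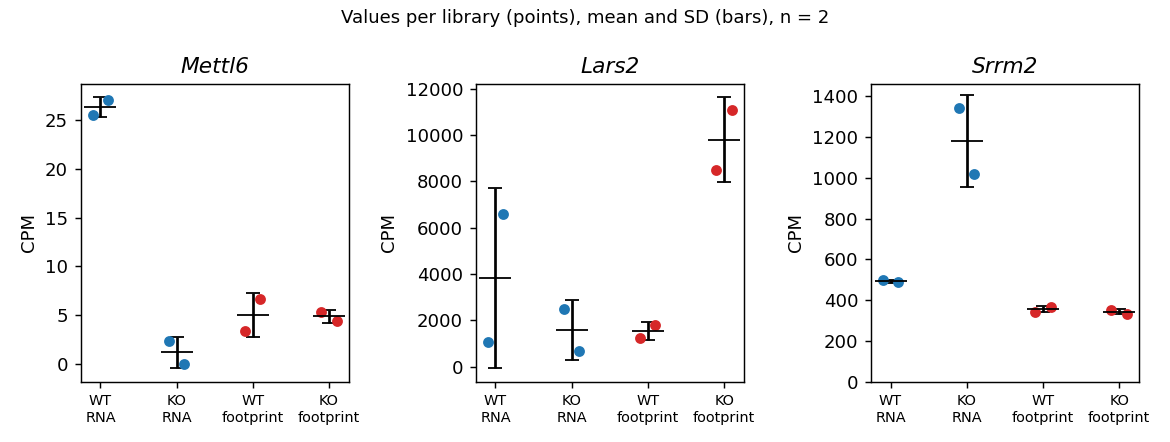
CPM of Mettl6, Lars2 and Srrm2 in each library (points), with the mean (horizontal line) and SD (bars) of the 2 libraries of each group, total RNA in blue and footprints in red. Mettl6 RNA goes from 25.6 and 27.1 CPM to 2.30 and 0 while its footprints stay between 3.38 and 6.59 CPM, Lars2 footprints rise to 8495 and 11096 CPM, and Srrm2 changes in total RNA.

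A pair of lists passed camera for translational efficiency. Of aminoacyl-tRNA synthetases, limma-trend called 0 of 22 genes (0 also when adjusted over the list alone, 20 of 22 above 0, median 0.39, adjusted p = 3e-04, and adjusted p = 0.881 with an estimated correlation). Of large-subunit ribosomal proteins it called 0 of 47 (0 also when adjusted over the list alone, 39 above 0, median 0.23, adjusted p = 0.00305, and adjusted p = 0.881 with an estimated correlation). The median of all genes was 0.07. The same lists had medians of −0.44 and −0.12 in total RNA and of −0.14 and 0.03 in footprints. Examples were Mars (log2 interaction 0.62, adjusted p = 0.404) and Aimp1 (0.71, 0.424) among synthetases and Rpl14 (0.82, 0.332) and Rpl34 (0.57, 0.456) among ribosomal proteins, none called. By limma-trend 1013 genes in all had an unadjusted p below 0.05, and fry called 0 lists, with 2 at an unadjusted p below 0.05. Between 1 and 10 lists passed with 1 library left out. The ribosomal protein list was lost without WT total RNA replicate 1, KO total RNA replicate 1 or WT footprint replicate 1, each of which left 1 list, and with the trend with transcript length removed. The integrated stress response (median 0.10, adjusted p = 0.608), genes buffered by upstream reading frames (−0.11, adjusted p = 0.471) and selenoproteins (median −0.03, mean 0.11, test up, adjusted p = 0.9), which are groups under translational control, did not pass.

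Within WT cells, footprints and total RNA differed in the genes they held. Of 11364 genes, 6984 differed between the kinds of library, 838 higher in footprints and 6146 lower, with a median log2 ratio of −0.87. The split depends on the scaling, since Rn45s took 46.3% and 41.3% of WT footprints and 2.49% and 6.46% of WT total RNA. With CPM recomputed without Rn45s, a setting chosen after the data were seen, 5738 genes differed, 2253 higher in footprints and 3485 lower, with a median of −0.192. The lists were tested on the library total with Rn45s, a test of lists within WT that was not planned. Replication-dependent histones were higher in footprints, 22 of 28 genes, with 2 lower (median 1.24, adjusted p = 8.67e-24, and adjusted p = 0.317 with an estimated correlation). Noncoding RNAs lay lowest, with 17 of 19 lower and 0 higher (median −3.89, adjusted p = 3.8e-07, and adjusted p = 0.505 with an estimated correlation). Malat1 stood at 4592 ± 290 CPM in total RNA and 39.0 ± 5.18 CPM in footprints (SD, n = 2). Nuclear-encoded genes of oxidative phosphorylation had 17 of 53 higher and 15 lower (median 0.17, adjusted p = 7.68e-08, and adjusted p = 0.571 with an estimated correlation). In all 11 lists passed camera here, and with an estimated correlation 0 passed, with 3 at an unadjusted p below 0.05. The median ratio was −0.87 for 10580 protein-coding genes and −1.16 for 110 long noncoding RNAs.

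Because METTL6 is known to act on serine tRNAs, the share of serine codons in each coding sequence was set against the changes, as a description across genes. For the change in translational efficiency, Spearman's rho with the serine share was −0.126 over 10921 genes, the second lowest of 20 amino acids after proline (−0.149). Each of the serine codons had a rho below 0, from −0.0974 for AGC to −0.0327 for TCT. The 2731 genes with the lowest serine share had a median change in translational efficiency of 0.14 and the 2722 genes with the highest one of −0.05. The footprint change had a rho of −0.0271 with the serine share, and the total RNA change one of 0.0846, the highest of the 20 amino acids. Given coding length and third-position GC these were −0.0526 and 0.0545. Given transcript length, a setting chosen after the data were seen, they were −0.053 and 0.0453. Transcript length itself had a rho of 0.178 with the total RNA change. With replicate 1 of every group left out the rho with translational efficiency was −0.0622, and without replicate 2 it was −0.129. In the same order the rho was −0.005 and −0.0437 with the footprint change, and 0.0598 and 0.0858 with the total RNA change.

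**Figure D5:**
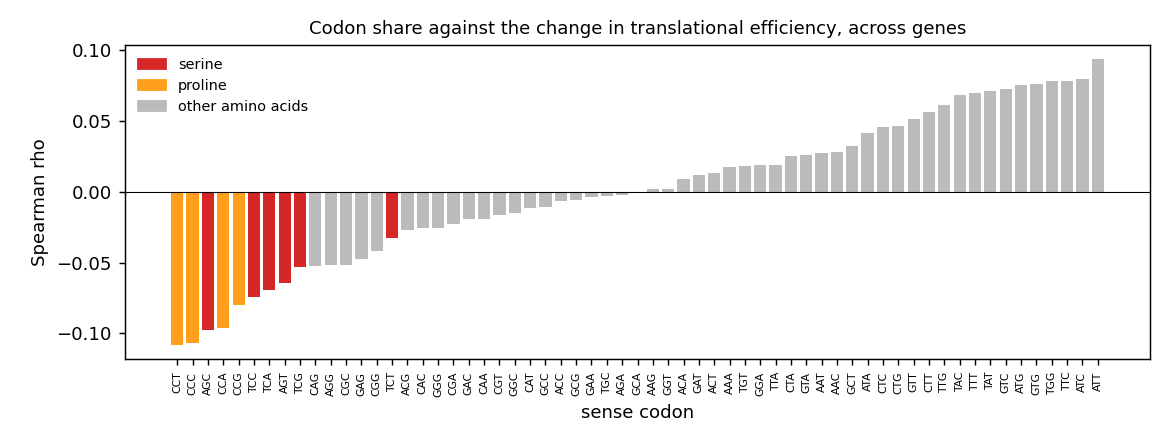
Spearman's rho across genes between the share of each of 61 sense codons in the coding sequence (horizontal axis, ordered by rho) and the change in translational efficiency (vertical axis), with serine codons red, proline codons orange and others grey. Serine codons lie between −0.0974 and −0.0327.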

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

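The interaction of genotype and kind of library and the correlations of the serine share, also given coding length and third-position GC, were planned. The other tests in this part, and the limits of every test of an explanation, were chosen after the results were seen.

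The KO against WT change differed between footprints and total RNA for 7 genes, by a tested interaction on the log2 scale. They were Mettl6 (3.93), Lars2 (3.75), Gm20594 (2.62), Rpph1 (2.47), 6820431F20Rik (1.72), Srrm2 (−1.29) and 4930470H14Rik (−1.44). Gm20594, 6820431F20Rik and 4930470H14Rik were named after their values were seen. Rpph1 is a noncoding RNA, so its interaction does not measure translation. A limma fit of ratios per replicate number gave an adjusted p of 0.67 for Mettl6, Lars2, Rpph1 and Srrm2, though the numbers were not shown to pair. Only Rpph1 of the 4 genes named by rule, Mettl6, Lars2, Rpph1 and Srrm2, kept an adjusted p below 0.05 with each library left out in turn.

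Genes of chromosomes 6, 8 and 11 lay lower in KO in both kinds of library. These chromosomes were picked by medians below −0.3 in both, so their footprints were part of the choice. Total RNA alone picks the same chromosomes, as no other had a total RNA median below −0.0996. On that choice the footprints (median −0.437 over 2173 genes) argue against a difference between the total RNA libraries, whose titles differ by genotype, as the whole cause. Transcript length, GC content or expression level left a difference of −0.44 once regressed out, and local gene clusters are argued against by the 99% of 96 windows that lie below 0. An extra copy of all 3 chromosomes in every WT cell, with RNA in proportion, would give −0.585, and their pooled median at 50 CPM or more, relative to other chromosomes, was −0.483 (bootstrap over genes −0.53 to −0.446, 823 genes). Resampling genes does not measure the spread between cultures, so these intervals hold for these libraries only. Taken singly, chromosome 8 (−0.421, bootstrap −0.482 to −0.369) argues against such a copy in these libraries. Its median ran from −0.47 to −0.427 with 1 library left out. Chromosome 6 (−0.549, −0.612 to −0.44) has the value such a copy needs, and chromosome 11 (−0.497, −0.576 to −0.454) leaves it open, since its lower bound reached −0.583 with 1 library left out. A copy gained by part of the WT cells, a copy lost by part of the KO clone and dosage that is buffered could each give such values, and stay open, as does an effect of the missing enzyme, since genotype and clone are the same here.

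Mettl6 kept its footprints in KO while its RNA nearly vanished. Footprint libraries labelled KO but made from WT cells are argued against by the median of −0.437 on chromosomes 6, 8 and 11 in these libraries. Footprints were part of the choice of these chromosomes, but total RNA alone picks the same ones. Of 5631 coding genes of similar length, with as little KO RNA, 21 (0.373%) had as many KO footprints, so such footprints are uncommon. These genes had a median of 0 CPM in KO footprints, and Mettl6 was taken up here because its footprints stood out against its RNA. The comparison therefore cannot decide on footprint background in genes without RNA. Reads of Eaf1, which shares 139 exonic bases, cannot be told apart from reads of Mettl6 in a table without positions. Footprints from an altered Mettl6 transcript, and reads from other genes that hold 987 of its 7833 words of 25 bases, stay open and were not tested.

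Coding sequences rich in serine codons had a lower change in translational efficiency. Coding length and third-position GC left a partial rho of −0.113, and the proline share left −0.0921, so neither accounts for the whole of it. Whether it comes from total RNA rather than from footprints cannot be told apart, since the serine share had a rho of −0.0271 with the footprint change and 0.0846 with the total RNA change, but −0.0526 and 0.0545 given coding length and third-position GC. An effect of the missing enzyme stays open and was not tested, as these values hold no positions of ribosomes on codons.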

How the results depend on the processing

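Settings with Rn45s left out, without the genes of chromosomes 6, 8 and 11, with every chromosome's median removed, with the length trend removed, left-out libraries in the fit of all libraries, quantile normalization of the lists, partial correlations given transcript length or proline share, and all settings of the chromosome medians were chosen after seeing the data. Outside left-out libraries, 333 of 349 values of named genes in total RNA, 355 of 365 in footprints and 99 of 126 for translational efficiency kept direction and side of the threshold. In total RNA 1799 calls became 937 with no filter and 1182 without the genes of chromosomes 6, 8 and 11 (fewer genes tested), and ran from 0 to 1888 with 1 library left out (fewer samples). In footprints 2205 became 1409 without those genes and ran from 574 to 2214. For translational efficiency 7 became 3 with no filter, 4 at 10 CPM or more, 2 and 14 with pseudocounts 0.1 and 5, 12 without Rn45s, 4 without those chromosomes, 11 with chromosome medians removed, 14 with the length trend removed, and 2 to 46 with 1 library left out. Lists past camera numbered 0 in total RNA, footprints and translational efficiency with an estimated correlation, and 10, 0 and 0 with fry. For translational efficiency they were 4 with quantile normalization, 1 with the length trend removed and 1 to 10 with 1 library left out, and in footprints 6 to 10. The WT ratio gave 4511 calls at 10 CPM or more (fewer genes tested) and 5738 without Rn45s, 2253 of them higher in footprints against 838. The correlation of footprint and total RNA changes was 0.735 at 10 CPM or more. Between different replicate numbers it was 0.451 and 0.456, from 1 library per group (fewer samples), where the main value took means of 2. The rho of serine share was −0.18 at 10 CPM or more and −0.129 to −0.0622 with 1 number left out. The median on chromosomes 6, 8 and 11 was −0.325 (total RNA) and −0.321 (footprints) with pseudocount 5, and −0.531 in footprints without Rn45s. Signs turned only for genes not called. In total RNA these were Mettl2 (0.0412, chromosome medians removed) and Pou5f1 (0.0755, length trend removed), and with 1 library left out Pou5f1 (−0.202 to 0.0173), Klf4 (−0.000668 to 0.249) and Esrrb (−0.174 to 0.0369). In footprints they were Mettl6 (−0.00296 with pseudocount 5, −0.053 without Rn45s, −0.0107 with chromosome medians and −0.000217 with the length trend removed, −0.382 to 0.412 with 1 library left out) and Sox2 (−0.0439 with quantile normalization, −0.07998 without Rn45s, −0.0157 with chromosome medians removed, −0.0920 to 0.101 with 1 library left out), and with 1 library left out Mettl8 (−0.305 to 0.0434) and Sars (−0.16 to 0.064). Except where fewer genes or samples are named, the cause was not tested. Replicate numbers were not shown to pair (correlations of deviations −0.0865 to 0.0898), and a replicate block gave 2056, 1833 and 11 calls, a block by genotype and number 9, and ratios per number 0 for translational efficiency by limma (802 at an unadjusted p below 0.05). Alternatives for counts were not run, since counts could not be recovered. At 1301531 to 2960255 reads, changes of 2-fold in translational efficiency were recovered for 43% of simulated genes at 5 CPM or more. The simulation gave all genes of a kind of library the same dispersion, so recovery in the real data can be lower.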

Other observations

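Gm25018, a 5S-type ribosomal RNA row outside the rule for named genes and chosen after its values were seen, stood at 4413 and 5293 CPM in WT footprints and 8772 and 9324 CPM in KO footprints.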
